A study of Mus musculus with 12 samples.

How the data were processed

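RNA was measured on 12 one-colour Agilent whole mouse genome arrays (Cy3), with 1 array per sample and no pooling stated. Per the labels, resident macrophages were taken from the peritoneum of female Balb/c mice aged 8 to 12 weeks, with (cPLA2a+/+) or without (cPLA2a-/-) cytosolic phospholipase A2 alpha, the product of Pla2g4a. The cells adhered for 2 h, were kept overnight, and were then left unstimulated or given Candida albicans at a multiplicity of 2 for 3 h. The RNA integrity numbers given in the labels run from 8.1 to 10. The labels name 3 independent experiments, so p-values here measure the spread between samples of a group. How many mice stand behind each sample is not given in the sources used here.

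The deposited array files hold spot intensity from Agilent Feature Extraction 10.7.1.1 (protocol GE1_107_Sep09, probe positions on genome build mm9). The authors' processed signal in them is an intensity after spatial detrending and background adjustment, with no scaling between arrays. The same files give the raw median intensity of spot and local background, and other columns that hold 0 or 1 flags (other units) for spots well above background, saturated or not uniform, per the file headers. The authors' value table was deposited as log2 values. It was checked against the files: over 16620 probes that were compared, each of its columns had a slope of 0.998 to 1.00 and a correlation of at least 0.99975 with the log2 processed signal after a shift by the array's 75th percentile and centring on each probe's median. Files of 8 arrays hold fewer columns than those of the other 4, and gene names stand in 4 files alone. Names were therefore joined by probe and brought to current symbols with a table of RefSeq names: 25089 probes by accession, 6339 by symbol, 1639 by an older symbol, and 8107 with the name in the file kept.

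Each array held 43379 non-control spots. Log2 of the processed signal was taken, the array's 75th percentile over these spots was subtracted, spots with an outlier flag were left out (61 to 118 per array), and spots of 1 probe were averaged, which gave 41174 probes and 27729 gene names. Each gene was represented by its brightest probe. A gene was kept if that probe was well above background on all arrays of at least 1 group, which left 18139 genes. Where a gene was well above background on no array of a group, a fold is given as a lower bound, with each of those arrays set at its lowest signal that was well above background or at the measured level if that was higher.

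Groups came from the sample labels alone. The 5 comparisons were the response to the yeast in each genotype, the genotype difference in unstimulated and in stimulated cells, and the interaction, that is the response in cPLA2a-/- cells minus that in cPLA2a+/+ cells. They were fitted with limma 3.58.1 (lmFit, contrasts.fit, eBayes) in R 4.3.3, with 1 coefficient per group and Benjamini-Hochberg adjustment over genes. A gene was called at an adjusted p under 0.05. Tables and plots were made with python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

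A set of 29 gene lists was fixed beforehand. They cover eicosanoid genes, other phospholipases A2, cAMP-responsive genes, inflammatory cytokines, anti-inflammatory feedback, chemokines, NF-kappaB targets, interferon-stimulated genes, fungal recognition, complement, metal handling, alternative activation, antigen presentation, sterol genes, oxidant defence, glycolysis and hypoxia, endoplasmic reticulum stress, heat shock, proliferation, lysosome, and matrix and coagulation. The others are markers of resident peritoneal macrophages and of B cells, T and natural killer cells, mast cells, eosinophils, neutrophils, mesothelial cells and dendritic cells. Lists with at least 5 kept members were tested with camera at its preset correlation of 0.01, and again with an estimated correlation and with fry; 28 lists qualified, since the eosinophil list had too few. Some lists share members (Il10 stands in the cAMP and feedback lists, Cd40 in the antigen presentation and NF-kappaB lists), so the lists are not independent of one another.

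Genes are named by a fixed rule. It takes, per comparison, the 10 largest rises and the 10 largest falls among called genes with a symbol and non-overlapping groups, or the 10 with the smallest p if fewer than 10 genes were called. It adds up to 2 rising and 2 falling called members per list with the smallest p, and Pla2g4a, Ptgs1, Ptgs2, Il10, Tnf, Il1b, Il6, Nr4a2, Ccl2 and Cxcl1 in every comparison. The text gives a part of these and describes the others by their lists. The values of 1 gene that the rule names are not reported here. These comparisons, lists, naming rules and the alternative settings listed first in the next paragraph were chosen before the data were examined.

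The alternatives were normexp background correction (offset 50, on the median signal because 8 files lack the mean signal), quantile and median scaling, the deposited log2 values, no filter or a filter over all 12 arrays, every probe on its own or the mean of a gene's probes, the arrays of the compared groups alone, trend and robust moderation, array weights, replicate number as a block or random term, slide and scan day as blocks, an added minimum change of 2-fold, and leaving out each array and each replicate number. The arrays were scanned on 2 days and stood on 5 slides, as the file headers show, and each day holds arrays of all 4 groups. As labelled, no slide holds both states of cPLA2a-/- cells. The response of that genotype, also where it is compared with that of cPLA2a+/+ cells, therefore rests on differences between slides. The second day holds replicate 1 of every group and the first day replicates 2 and 3. The scan day block therefore cannot be told apart from a difference between replicate 1 and the others. Values within the second day rest on 1 array per group. Once the arrays labelled cPLA2a-/- replicate 3 are left out, each day has 1 cPLA2a-/- array per state.

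The arrays labelled cPLA2a-/- unstimulated replicate 3 and cPLA2a-/- stimulated replicate 3 stood apart from their groups. The comparisons as planned keep them under their labels. After this was seen, fits without these 2 arrays were added: 10 arrays (18914 genes), 10 arrays with scan day as a block, and 10 arrays with slide as a random term. The list tests on the 10 arrays were also run with quantile and with median scaling. No comparison is given with the 2 labels exchanged, apart from 1 of the splits of the 6 cPLA2a-/- arrays in the closing section, which amounts to that.

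The procedure was tested on simulated data, made of normal noise with each gene's fitted spread around its mean, to which changes were added. With 12 arrays, 2% of genes raised or lowered 2-fold were called in the cPLA2a+/+ response and 51% of those changed 4-fold, with 5 false calls. For the interaction the shares were 0% and 20%. A raised set of 24 genes was called in all 15 simulated comparisons, with 0 false calls among 28 other sets. The noise was drawn independently for each gene. The simulation therefore cannot show how often camera calls an unchanged list whose members are correlated. Protein and lipid mediators were not analysed here.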

Results

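Gene expression was measured in resident peritoneal macrophages, the phagocytes that can be washed out of the abdominal cavity, from mice with and without cytosolic phospholipase A2 alpha (cPLA2a). This enzyme releases arachidonic acid, the precursor of prostaglandins and leukotrienes, from membranes. Cells of both genotypes were left unstimulated or met the yeast Candida albicans for 3 h, which gave 4 groups of 3 arrays. Between 56.1% and 76.6% of the spots of an array were well above background, and 0 spots were saturated. By group the share was 68.5% ± 7.20 (SD, n = 3) in unstimulated cPLA2a+/+ cells, 64.2% ± 5.81 after the yeast, 67.2% ± 8.88 in unstimulated cPLA2a-/- cells and 63.5% ± 7.58 after the yeast. The 8 arrays of 1 scan day ranged from 56.1% to 69.0% and the 4 arrays of the other day from 70.9% to 76.6%, and each day held all 4 groups. The number of arrays limits the precision of every value.

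Pla2g4a, the gene that was disrupted, was examined first. Its signal (probe A_51_P402760, chromosome 1, 151677133 to 151677192 on mm9, minus strand) was 1.07 ± 0.53 in unstimulated cPLA2a+/+ cells and 3.53 ± 0.47 after the yeast, in log2 units above the array's 75th percentile (SD, n = 3). In the cPLA2a-/- groups as labelled it was -0.28 ± 2.15 and 0.83 ± 1.83 (SD, n = 3). This wide spread came from 1 array in each group. The unstimulated arrays stood at -1.70, -1.34 and, on the array labelled replicate 3, 2.18. The stimulated arrays stood at 1.66, 2.09 and, on the array labelled replicate 3, -1.28. The means without these 2 arrays were -1.52 ± 0.26 and 1.88 ± 0.31 (SD, n = 2). A second probe (A_52_P660648, 151677294 to 151687778) gave 0.00 ± 0.46 and 2.47 ± 0.37 in cPLA2a+/+ cells and, without the 2 arrays, -2.66 ± 0.04 and 0.79 ± 0.03 in cPLA2a-/- cells. On these arrays both probes read lower in cPLA2a-/- than in cPLA2a+/+ cells and stayed well above background. Which part of the gene was deleted is not given in the sources used here.

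**Figure D1:**
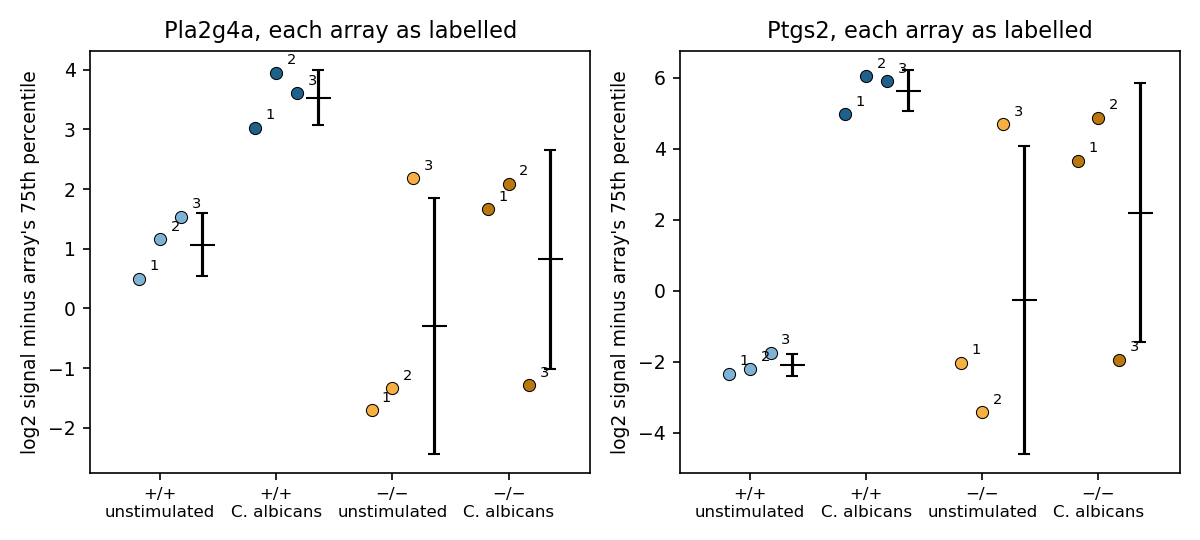
Pla2g4a signal on each array, in log2 units above the array's 75th percentile, by group. Points are arrays with their replicate number, lines and bars are the mean ± SD of the 3 arrays as labelled; the arrays labelled replicate 3 lie at 2.18 among unstimulated and at -1.28 among stimulated cPLA2a-/- arrays.

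The same 2 arrays stood apart across the genome. Along an axis through 3249 genes that changed in cPLA2a+/+ cells, on which the other unstimulated cPLA2a-/- arrays average 0 and the other stimulated ones average 1, the array labelled unstimulated replicate 3 lay at 1.11. The array labelled stimulated replicate 3 lay at -0.04. The 6 cPLA2a+/+ arrays took no part in setting the scale and lay at -0.04 to 0.07 when unstimulated and at 1.03 to 1.15 when stimulated. The genes of the axis were chosen by their difference between these same 6 arrays, so this separation is no independent check. The comparisons keep both arrays under their labels, and each is followed by the value without them (10 arrays), a choice made after the data were seen. The difference between the cPLA2a+/+ groups is the same in the fits of 12 and of 10 arrays without a block or weights, and its test was also run on these 6 arrays alone, as planned.

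**Figure D2:**
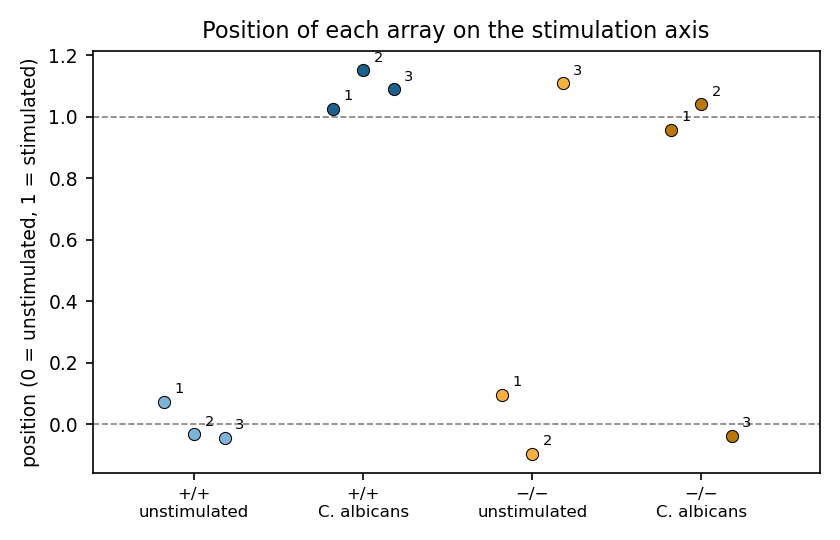
Position of each array on the axis from unstimulated (0) to stimulated (1) over 3249 genes. Both ends are fixed by the means of the arrays labelled cPLA2a-/- replicates 1 and 2; the arrays labelled cPLA2a-/- replicate 3 lie at 1.11 and -0.04, each among arrays of the other state.

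The first comparison asked what cPLA2a+/+ macrophages do within 3 h of meeting the yeast. Csf3, the granulocyte colony-stimulating factor, rose by 9.30 ± 0.51 on the log2 scale (SE, 3 against 3 arrays), the epidermal growth factor receptor ligand Hbegf by 7.80 ± 0.54, and the activin subunit Inhba by 7.22 ± 0.51. Csf2, the granulocyte-macrophage colony-stimulating factor, and Areg, another ligand of the epidermal growth factor receptor, were well above background on 0 unstimulated arrays and rose at least 189-fold and at least 156-fold. Ptgs2, the inducible cyclooxygenase, rose by 7.73 ± 0.34 and F3, tissue factor, by 7.48 ± 0.44. Ppp1r3g, a glycogen-targeting subunit of protein phosphatase 1, rose at least 76.9-fold. The adjusted p of these 8 genes on the 6 arrays lay between 0.000409 and 0.00209. Pla2g4a itself rose by 2.46 ± 0.36 (adjusted p = 0.00749).

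Cytokines of the acute response rose with them: Il6 by 6.74 ± 1.07, Il10 by 6.25 ± 0.69, Tnf by 4.85 ± 0.40 and Il1b by 2.95 ± 0.59 (SE, 3 against 3 arrays). The chemokines Ccl7, Ccl2 and Cxcl1 rose by 6.75 ± 0.79, 4.94 ± 0.89 and 4.63 ± 0.41, and the nuclear receptor Nr4a2 by 6.31 ± 0.51. Adjusted p ran from 0.00162 for Nr4a2 to 0.0187 for Il1b. Ptgs1, the constitutive cyclooxygenase, differed by -0.74 ± 0.49 (adjusted p = 0.359). Falling genes changed less in size. Engase, a cytosolic glycosidase, fell by 4.06 ± 0.57, Bmf, a pro-apoptotic member of the BCL2 family, by 3.39 ± 0.52, Ahrr, the repressor of the aryl hydrocarbon receptor, by 3.17 ± 0.58, and Rin2, a regulator of RAB5, by 3.06 ± 0.36. The potassium channel Kcnj10 and the zinc finger gene Zkscan4 were well above background on 0 stimulated arrays, at least 11.6-fold and at least 4.77-fold lower. Adjusted p of these falls lay between 0.00173 and 0.0149.

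On the 6 cPLA2a+/+ arrays alone limma called 3252 of 17508 genes, 1491 higher and 1761 lower. Fitted with all 12 arrays as labelled, 9 of 18139 genes were called, all higher (3896 at an unadjusted p under 0.05). They include Slco2b1, an organic anion transporter (at least 5.43-fold higher, adjusted p = 0.00115), Asb4, Gpalpp1, Crem, a cAMP-responsive repressor, Abca1, a cholesterol exporter, Fosl2 and Thap2. Once the 2 arrays were left out, 3320 of 18914 genes were called, with the 9 among them, and 5475 with scan day as a block. On the first scan day alone (6 arrays, without the 2) 2016 genes were called, of which 1991 (98.8%) had the same direction on the second day; with all 8 arrays of the first day as labelled 0 were called (1978 at an unadjusted p under 0.05, smallest adjusted p = 0.241). Within each of the slides that hold both states of this genotype, 3252 of the 3252 genes had the direction of the 6-array fit; these pairs are part of that fit.

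Among the fixed lists, cAMP-responsive genes, glycolysis and hypoxia genes and NF-kappaB targets moved together in cPLA2a+/+ cells. Of 34 cAMP-responsive genes 22 rose, 0 fell and 12 were not called (10 arrays; 25 rose when adjusted over the list alone), with Vegfa, the vascular growth factor, up by 5.13 ± 0.29 and the GTP-binding protein gene Gem by 5.99. Of 24 glycolysis and hypoxia genes 18 rose and 6 were not called (21 adjusted over the list alone), with the glucose transporter Slc2a1 up by 4.44 ± 0.26 and hexokinase Hk2 by 4.16 ± 0.26. Of 30 NF-kappaB targets 21 rose and 9 were not called (25 adjusted over the list alone), among them Cd83 by 4.43 and Nfkb1 by 2.57. Over all 12 arrays camera called the 3 lists, with medians of 2.51, 1.91 and 1.34 and adjusted p of 5.78e-16, 1.51e-10 and 5.19e-12. None of these calls held with an estimated correlation on 12 arrays (adjusted p = 0.427 for each) or on 10 (0.086 to 0.128), while all 3 did with quantile scaling of the 10 arrays (adjusted p of 0.0456 to 0.0457 with an estimated correlation). Within the scan days the medians were 2.81 and 2.00 for the cAMP list, 1.80 and 2.05 for glycolysis and 1.60 and 1.08 for NF-kappaB targets.

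Inflammatory cytokines (13 of 24 rose with 10 arrays, 14 adjusted over the list alone) included Il1a, up by 5.77 ± 0.34, and Osm, up by 3.73. Of 23 anti-inflammatory feedback genes 15 rose and 1 fell (15 and 1 adjusted over the list alone): the interleukin 1 antagonist Il1rn by 5.65 ± 0.25, Socs3 by 4.01, and the inhibitory receptor Cd200r1, which fell by 1.87. Of 25 chemokines 10 rose (11 adjusted over the list alone), with Ccl4 up by 5.84 ± 0.37 and Ccl3 by 4.13 ± 0.24. Of 28 matrix and coagulation genes 11 rose and 0 fell (14 and 2 adjusted over the list alone), with the stromelysin Mmp3 up by 4.53. Endoplasmic reticulum stress genes (10 of 18, 11 adjusted over the list alone; Chac1 by 3.74, Ppp1r15a by 3.22) and heat shock genes (5 of 14, 9 adjusted over the list alone; Hsph1 by 1.90) rose too. With 12 arrays camera called these 6 lists with medians of 0.86 to 1.59 and adjusted p of 1.50e-07 to 0.000196. With an estimated correlation the adjusted p was 0.427 for cytokines, feedback genes and matrix genes and 0.506 for the other lists; with quantile scaling of the 10 arrays it was 0.0456 to 0.0457 for cytokines, matrix genes and endoplasmic reticulum stress genes.

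Smaller shifts were called for alternative activation (median 0.72; with 10 arrays 3 of 18 rose, 6 adjusted over the list alone, Irf4 by 2.70 and Arg1 by 1.71) and oxidant defence (median 0.32; with 10 arrays 7 of 22 rose, 7 adjusted over the list alone, Txnrd1 by 2.28). With 12 arrays 0 members of either were called, and adjusted p was 0.0362 and 0.0271, or 0.653 and 0.651 with an estimated correlation. Interferon-stimulated genes moved the other way with 12 arrays (median -0.58, adjusted p = 0.00197, but adjusted p = 0.651 with an estimated correlation). With 12 arrays 0 members were called; with 10 arrays 6 of 35 fell and 1 rose (6 and 1 adjusted over the list alone): Usp18, which removes ISG15 from proteins, fell by 2.63 and the immunity-related GTPase Igtp by 1.45, while Isg15 rose by 3.73. Metal handling genes were called without the 2 arrays (median 0.38, 7 of 20 rose and 1 fell, the same adjusted over the list alone; adjusted p = 0.0149, and adjusted p = 0.221 with an estimated correlation), with the metallothionein Mt2 up by 4.35 ± 0.25; with 12 arrays the adjusted p was 0.0929.

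The lists closest to the enzyme were not called in cPLA2a+/+ cells. With 10 arrays, of 30 eicosanoid genes (median -0.10) 4 rose and 2 fell (4 and 2 adjusted over the list alone): beside Ptgs2, the prostaglandin E synthase Ptges rose by 2.41 ± 0.22 and the prostacyclin receptor Ptgir by 1.51, while the leukotriene A4 hydrolase Lta4h fell by 0.93. Of 16 other phospholipases A2 (median -0.02) 2 rose (2 adjusted over the list alone), Pla2g5 by 2.13 and Pla2g12a by 0.65. Not called either were antigen presentation (median 0.31, 4 of 18 rose, 4 adjusted over the list alone, Cd86 by 1.94), fungal recognition (-0.03; 6 rose and 2 fell of 35, 6 and 2 adjusted over the list alone, Malt1 up by 3.68), complement (0.04; C3ar1 of 18 fell, by 1.69, 1 adjusted over the list alone), sterol genes (-0.22; 1 rose and 4 fell of 26, 1 and 4 adjusted over the list alone, the exporters Abca1 up by 2.03 and Abcg1 down, which fell by 2.25), proliferation (-0.24; 2 rose and 1 fell of 18, 3 and 2 adjusted over the list alone) and lysosomal genes (-0.02; 1 rose and 2 fell of 29, 1 and 1 adjusted over the list alone). Their camera adjusted p lay between 0.0973 and 0.958 without the 2 arrays.

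Markers of the resident macrophage (median 0.02; 2 rose and 1 fell of 24, 2 and 1 adjusted over the list alone) and of other peritoneal cells were not called in this response. Medians with 10 arrays were 0.06 for 12 mast cell markers (Hdc, histidine decarboxylase, rose by 4.71 ± 0.35 and 11 were not called; 1 adjusted over the list alone), 0.16 for 11 B cell, -0.09 for 13 T and natural killer cell, -0.16 for 8 neutrophil, 0.52 for 9 mesothelial and 0.23 for 9 dendritic cell markers. B cell, mesothelial and dendritic markers had 0 members called with limma on 10 arrays, T cell markers 1 rising and 1 falling, and neutrophil markers 1 falling, with the same numbers adjusted over the list alone. Of the eosinophil list 4 members were kept, too few for a test; Prg2 differed by 0.60, Siglecf by 0.33, Epx by 0.31 and Ccr3 by 0.01.

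The second comparison asked which of these changes occur in cells that lack the enzyme. As labelled, limma called 0 of 18139 genes (334 at an unadjusted p under 0.05, smallest adjusted p = 1), with Ptgs2 at 2.45 ± 2.00 and Pla2g4a at 1.11 ± 1.03 (SE, 3 against 3 arrays). Among the 10 arrays left when those that stood apart are set aside, 1195 of 18914 genes were called, 677 higher and 518 lower (2 against 2 arrays), and 3208 with scan day as a block. The unstimulated and the stimulated arrays of this genotype stood on different slides. Within these arrays alone a difference between slides cannot be told apart from the response. On the first scan day alone (1 stimulated and 1 unstimulated array of this genotype) limma called 0 genes (4382 at an unadjusted p under 0.05, smallest adjusted p = 0.0509).

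The changes below come from the fit of 10 arrays. Ppp1r3g rose at least 90.6-fold, Csf3 by 7.34 ± 0.66, Ptgs2 by 6.99 ± 0.58, Csf2 by 6.90 ± 0.73, Ccl7 by 6.73 ± 0.86 and F3 by 6.63 ± 0.57 (SE, 2 against 2 arrays). Gdf15, a stress-induced cytokine, rose by 6.40 ± 0.67 and the immediate early gene Egr1 by 6.28 ± 0.68. Tnf rose by 6.19 ± 0.53, Ccl2 by 5.23 ± 1.03, Cxcl1 by 4.88 ± 0.52, Nr4a2 by 3.67 ± 0.57 and Pla2g4a by 3.40 ± 0.41. Adjusted p of these genes ran from 0.000121 to 0.0256. Engase fell by 4.20 ± 0.74, Bmf by 3.50 ± 0.78 and Thbd, thrombomodulin, by 3.21 ± 0.56, while Bahcc1 and Axin2, a feedback gene of Wnt signalling, were at least 6.71-fold and at least 3.57-fold lower (adjusted p from 0.00737 to 0.0489). Il10 at 2.56 ± 0.77, Il1b at 2.51 ± 0.73, Il6 at 4.77 ± 1.35 and Ptgs1 at -0.20 ± 0.68 were not called (adjusted p of 0.0943, 0.0827, 0.0773 and 0.926).

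Over the lists, 16 of 24 glycolysis and hypoxia genes rose in cPLA2a-/- cells (10 arrays; 20 adjusted over the list alone), with Hk2 up by 4.87 ± 0.32. Of 30 NF-kappaB targets 11 rose (18 adjusted over the list alone), of 24 cytokines 10 (15; Il1a by 5.62 ± 0.42), of 34 cAMP-responsive genes 11 (18; Gem by 6.13 ± 0.48), and of 18 endoplasmic reticulum stress genes 9 (11). Of 23 feedback genes 5 rose and 1 fell (13 and 1 adjusted over the list alone; Il1rn rose by 5.46 ± 0.30), of 28 matrix genes 10 rose and 1 fell (10 and 1), and of 25 chemokines 6 rose (8; Ccl3 by 4.43). Their medians were 1.92, 1.33, 2.25 (1.85 with members below background at their bound), 1.75, 0.91, 1.11, 0.68 and 0.88, in this order, and camera called them at adjusted p from 2.48e-22 to 1.70e-06. With an estimated correlation the adjusted p lay between 0.0553 and 0.266, and with quantile scaling of the 10 arrays between 0.0341 and 0.0476 for glycolysis, NF-kappaB targets, cytokines, endoplasmic reticulum stress and matrix genes. Within the scan days the medians were 1.94 and 1.99 for glycolysis, 1.48 and 1.28 for NF-kappaB targets and 2.08 and 0.92 for the cAMP list. In all, camera called 14 lists without the 2 arrays and 10 with 12 arrays as labelled; among the latter were the same 8 lists, with medians of 0.28 to 0.94 and 0 members called (limma), at adjusted p from 4.61e-09 to 0.0108, but adjusted p = 0.626 with an estimated correlation. Interferon-stimulated genes had a median of 0.20 without the 2 arrays and were not called by camera (adjusted p = 0.207, with 2 of 35 rising and 0 adjusted over the list alone). Within the scan days their medians were -0.36 and 0.72. Mast cell markers had a median of 0.34 without the 2 arrays (1 of 12 rose, 1 adjusted over the list alone).

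The responses of both genotypes were set against each other across genes, which are not independent replicates. With 10 arrays Pearson's r was 0.733 over all 18914 genes (Spearman's rho 0.627) and 0.934 over the 3428 genes called in either response (rho 0.901), of which 98.2% had the same sign. The slope of the principal axis, cPLA2a-/- on cPLA2a+/+, was 0.872 through the latter and 0.978 through all 18914 genes. More genes were called in the cPLA2a+/+ response (3320) than in the cPLA2a-/- response (1195). The choice of genes can therefore lower the slope, which does not show a weaker response. Both responses shared 635 rising genes, where independent lists would share 54.2, and 452 falling genes against 49.4. As labelled, r was 0.45 (rho 0.407) over 18139 genes.

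**Figure D3:**
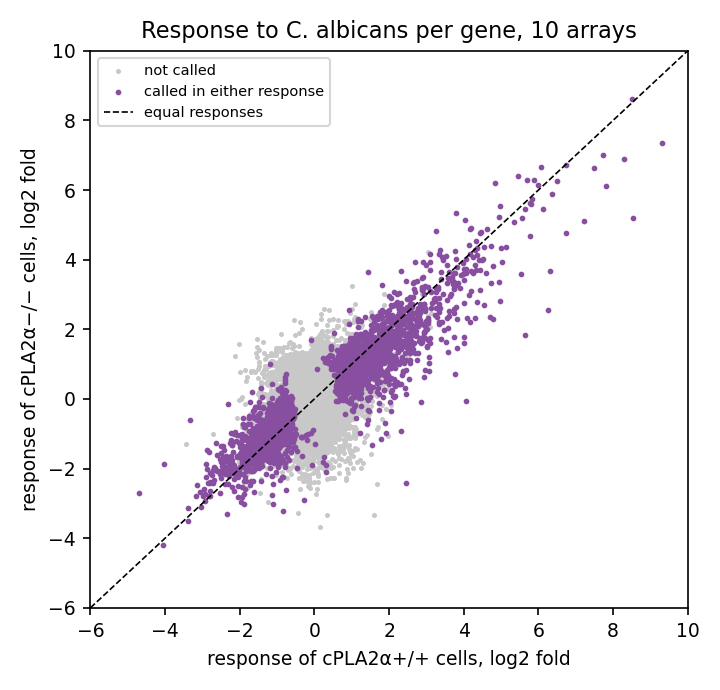
Response to the yeast in cPLA2a-/- cells (vertical axis, log2) against that in cPLA2a+/+ cells (horizontal axis, log2), 10 arrays, 1 point per gene. Purple points are the 3428 genes called in either response, with a correlation of 0.934, grey points the other genes, and the dashed line marks equal responses.

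The third comparison asked how cPLA2a-/- macrophages differ before they meet the yeast. Mast cell genes stood among those with the smallest p as labelled. Cma1, a chymase, was -3.00 ± 0.48 in cPLA2a-/- against cPLA2a+/+ cultures, Tpsb2, a tryptase, -2.97 ± 0.49, Cpa3, mast cell carboxypeptidase, -3.18 ± 0.54, and Mcpt4, another chymase, -1.93 ± 0.40 (log2, SE, 3 against 3 arrays). On the other side stood Gsta1, a glutathione transferase, at 2.53 ± 0.47, Tfrc, the transferrin receptor, at 1.57 ± 0.28, the chemokine gene Cxcl13 at 2.56 ± 0.49 and the scavenger receptor gene Marco at 2.52 ± 0.52. None of them passed the test: limma called 0 genes as labelled (248 at an unadjusted p under 0.05, smallest adjusted p = 0.458), 0 without the 2 arrays (398, 0.623) and 0 with scan day as a block (927, 0.113). Pla2g4a was at -1.35 ± 1.03 as labelled, at -2.59 ± 0.38 without the 2 arrays and at -2.69 and -2.20 within the scan days.

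As a list the 12 mast cell markers were lower (median -2.41 as labelled, and -1.91 with members below background at their bound), with 0 members called over all genes and 8 lower when adjusted over the list alone. Camera gave an adjusted p of 5.94e-24, which held with an estimated correlation (adjusted p = 0.0219), and fry gave 0.02. With replicate number as a block and an estimated correlation the call was lost, as camera then called 0 of 28 lists. On 10 arrays the median was -2.53 (9 lower adjusted over the list alone), with adjusted p = 0.0533 when the correlation was estimated. Within the scan days the medians were -2.70 and -2.01. The mean level of the 12 markers ranged from -0.84 to 0.78 over the 6 cPLA2a+/+ arrays and from -2.76 to -2.02 over the 6 cPLA2a-/- arrays, with the arrays labelled replicate 3 at -2.02 and -2.48. Markers of other cells differed less: without the 2 arrays the medians were -0.38 for B cells, -0.02 for T cells, -0.19 for neutrophils, 0.15 for mesothelial cells, 0.17 for dendritic cells and -0.08 for resident macrophages, none of them called in that fit. As labelled, camera called the neutrophil list lower (median -0.34, adjusted p = 0.0419, and adjusted p = 0.374 with an estimated correlation). Within the scan days the medians were 0.11 and -0.57 for B cells and -0.004 and -0.54 for neutrophils.

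**Figure D4:**
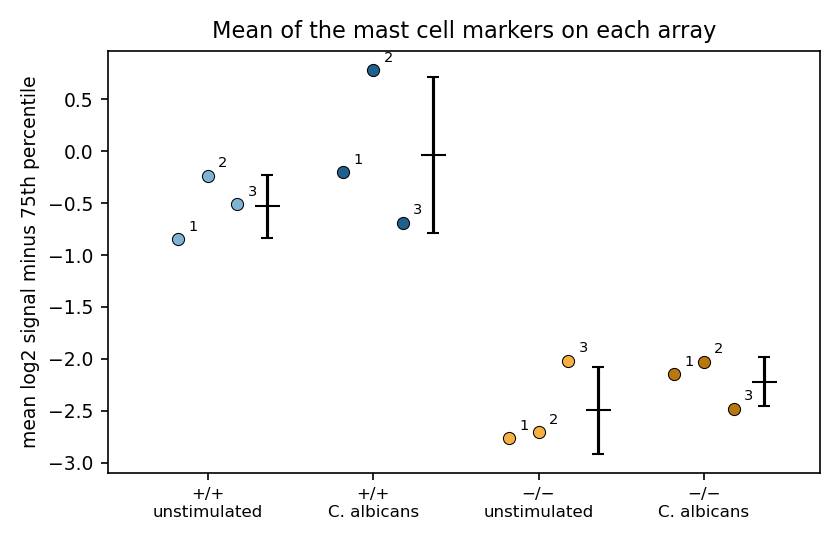
Mean log2 level of 12 mast cell markers on each array, relative to the array's 75th percentile, by group. Points are arrays with their replicate number and lines and bars the mean ± SD of the 3 arrays as labelled; the cPLA2a+/+ arrays lie between -0.84 and 0.78 and the cPLA2a-/- arrays between -2.76 and -2.02.

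As labelled, camera called 16 lists in unstimulated cells, most of them lists that also rose after the yeast, and 6 without the 2 arrays. With an estimated correlation 2 of the 16 were called, mast cell markers and metal handling, and the others had an adjusted p of 0.233 to 0.583. Metal handling genes, which include Tfrc, were higher (median 0.35, 2 of 20 higher when adjusted over the list alone, adjusted p = 6.14e-05, and adjusted p = 0.0499 with an estimated correlation; without the 2 arrays 0.0276 and 0.7). That call was lost with quantile scaling (adjusted p = 0.0533 with an estimated correlation) and without a filter (0.224). Oxidant defence genes were also higher without the 2 arrays (median 0.32, 21 of 22 positive), and so were interferon-stimulated genes (0.34, 30 of 35 positive), chemokines (0.49, with Ccl5 at 2.62 ± 0.46, 2 adjusted over the list alone) and NF-kappaB targets (0.14). Their camera adjusted p lay between 7.84e-06 and 0.0325 and was 0.715 to 0.945 with an estimated correlation, and no member was called over all genes, nor, apart from the 2 chemokines, when adjusted over the list alone. The interferon median was 0.68 within the first scan day and -0.03 within the second. The mast cell markers were lower on the same arrays, by a median of -2.53.

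The fourth comparison asked how the genotypes differ after the yeast. As labelled, limma called 9 of 18139 genes, 1 higher and 8 lower in cPLA2a-/- cells (1633 at an unadjusted p under 0.05). On the 6 stimulated arrays alone it called 0 (1480 at an unadjusted p under 0.05, smallest adjusted p = 0.123), and leaving out any 1 of these 6 arrays from the fit of 12 gave 0 to 3. Among the 9, Slco2b1, the organic anion transporter, was at least 4.25-fold lower (adjusted p = 0.00491), Crem, the cAMP-responsive repressor, fell by 3.33 ± 0.45, Asb4 by 2.66 ± 0.34, Qpct, a glutaminyl cyclase, by 2.57 ± 0.32, Pla1a, a phosphatidylserine-specific phospholipase, by 2.54 ± 0.31 and Bach2, a transcriptional repressor, by 2.01 ± 0.26 (SE, 3 against 3 arrays, adjusted p from 0.0243 to 0.0316). Amph was at least 3.88-fold lower, and Calhm6, an interferon-induced ion channel gene, rose by 2.34 ± 0.31. Of the genes named in every comparison, Il10 was at -4.89 ± 1.05, Nr4a2 at -3.68 ± 1.03, Pla2g4a at -2.70 ± 1.03 and Tnf at -0.24 ± 1.83, and none was called (adjusted p from 0.185 to 0.972).

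With 10 arrays 4 of 18914 genes were called, all lower: Hdc, histidine decarboxylase, fell by 4.34 ± 0.39, Frat2, which binds GSK3, by 1.96 ± 0.19 and the integrin gene Itga9 by 1.80 ± 0.18, and Slco2b1 was at least 4.20-fold lower (SE, 2 against 3 arrays, adjusted p of 0.0306 to 0.0336). Slco2b1 was the 1 gene called in both fits. With scan day as a block, 190 genes were called, 85 higher and 105 lower, and these held the 9 and the 4. Among them Hdc fell by 4.25 ± 0.29, Trem1, an amplifying receptor of myeloid cells, by 3.63 ± 0.42, Areg by 3.53 ± 0.52, Crem by 3.30 ± 0.48, Nr4a2 by 2.88 ± 0.44 and Pla2g4a by 1.55 ± 0.21. Timd4, a phosphatidylserine receptor of resident macrophages, rose by 2.63 ± 0.39, Cxcl13 by 2.53 ± 0.33, Ccl5 by 2.42 ± 0.27, the guanylate-binding protein gene Gbp6 by 2.39 ± 0.29 and C1s1, a complement protease, by 2.33 ± 0.23 (adjusted p of these from 0.0141 to 0.0403). Il10 at -3.88 ± 0.71 and Tnf at 2.04 ± 0.41 were not called (adjusted p = 0.0599 and 0.0717). Within the scan days the differences were -3.36 and -3.03 for Crem, -4.44 and -2.74 for Il10, 2.09 and 2.22 for Tnf, and 2.67 and 2.19 for Ccl5. Part of these genes also differed before the yeast, though not called there. Within the days Hdc stood at -2 and -1.80, Trem1 at -2.57 and -1.48 and C1s1 at 1.53 and 1.79. Cxcl13 stood at 2.74 and 2.70 and Ccl5 at 2.62 and 2.81. Crem (-0.95 and 0.46) and Nr4a2 (-0.52 and 0.13) changed sign between the days, and Areg was at -0.05 and -0.55.

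Of the lists, cAMP-responsive genes were lower and interferon-stimulated genes higher in stimulated cPLA2a-/- cells. As labelled, the 34 cAMP-responsive genes had a median of -1.16 (Crem fell, 33 were not called, 5 lower adjusted over the list alone) and camera gave an adjusted p of 1.79e-11; the adjusted p was 0.548 with an estimated correlation. On 10 arrays the median was -0.85 (0 called, 9 lower adjusted over the list alone), and within the scan days it was -0.87 and -0.70. With scan day as a block 5 of the 34 fell (12 adjusted over the list alone), Areg, Crem, Nr4a2, Rgs1 and Rgs2, the last pair being regulators of G protein signalling, by 2.18 and by 2.15. Rgs2 was less steady, at -1.28 with 12 arrays as labelled and at -0.57 without stimulated cPLA2a-/- replicate 1. The 34 interferon-stimulated genes had a median of 1.0 as labelled (0 called, 11 higher adjusted over the list alone), with adjusted p = 2.01e-13, and adjusted p = 0.407 with an estimated correlation. On 10 arrays the median was 1.07 over 35 members (13 adjusted over the list alone), and within the scan days it was 1.11 and 1.28. With scan day as a block 5 of the 35 rose (18 adjusted over the list alone), the guanylate-binding protein genes Gbp2 by 2.25, Gbp3 by 1.76 and Gbp5 by 1.32, Ifi47 by 2.01 and Irgm1 by 1.40; with an estimated correlation the adjusted p of both lists was 0.545 in this fit. The antiviral genes Rsad2 at 2.79 and Ifit1 at 2.49 were not called. Gbp5 kept its direction in the fits with 1 array or number left out, but ran from 0.54 to 1.42.

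Mast cell markers were lower on these arrays too: the median was -2.20 as labelled (0 called, 9 of 12 lower adjusted over the list alone; adjusted p = 5.18e-14, adjusted p = 0.111 with an estimated correlation and 0.0088 with fry). Within the scan days it was -2.13 and -2.07. On 10 arrays Hdc was called and the median was -2.23; with scan day as a block Hdc, Cma1 and Tpsab1 fell, by 4.25, 2.62 and 3.18 (10 adjusted over the list alone). As labelled, camera also called anti-inflammatory feedback (-0.69), matrix genes (-0.67) and NF-kappaB targets (-0.43) as lower and lysosomal genes (0.16) as higher, at adjusted p from 0.0209 to 0.0266, with 0 members called (limma; 3 feedback genes were lower when adjusted over the list alone), and each had adjusted p = 0.785 with an estimated correlation. None of these 4 was called without the 2 arrays, where the medians were -0.34, -0.13, -0.07 and 0.17. Oxidant defence genes were called there (median 0.27, 4 of 22 higher adjusted over the list alone; adjusted p = 0.00529, and adjusted p = 0.949 with an estimated correlation), with within-day medians of 0.43 and 0.29. Eicosanoid genes had a median of 0.15 as labelled and 0.09 without the 2 arrays and were not called (adjusted p = 0.536 and 0.814).

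**Figure D5:**
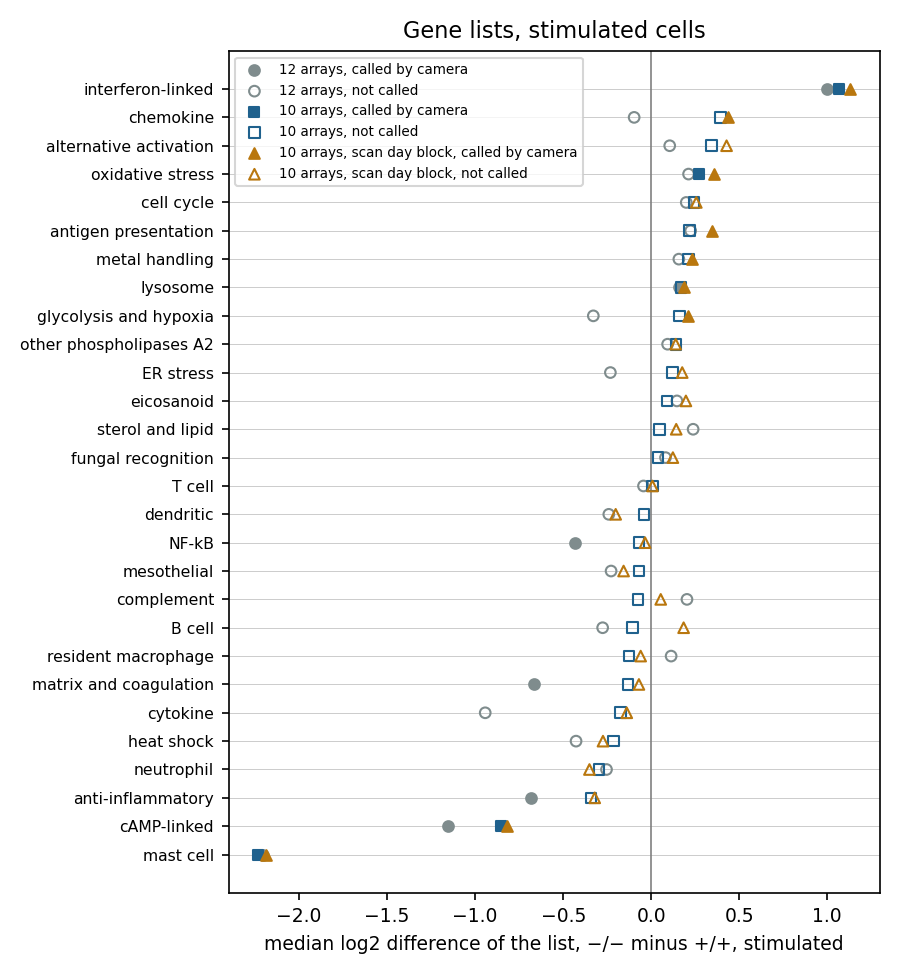
Median log2 difference, cPLA2a-/- minus cPLA2a+/+ after the yeast, over the members of each gene list, with 12 arrays as labelled, with 10 arrays, and with 10 arrays and scan day as a block. The mast cell list lies between -2.23 and -2.19, the cAMP list between -1.16 and -0.82, and the interferon list between 1.0 and 1.13.

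The interaction tested whether the response itself differed between genotypes. As labelled, limma called 1 gene (763 at an unadjusted p under 0.05): Slco2b1 (adjusted p = 0.0244). It was well above background on the 3 stimulated cPLA2a+/+ arrays and on 0 of the others, so 3 of the 4 group means in this test are signals near background and no size of the difference is given here. With normexp the fitted difference had the opposite sign, and the call was lost with scan day as a block on 12 arrays (adjusted p = 0.0512) and without a filter (0.0527). Asb4 at -2.71 ± 0.48, Crem at -3.40 ± 0.63, Il10 at -5.74 ± 1.48 and Nr4a2 at -4.71 ± 1.45 were not called (adjusted p = 0.805 each). With 10 arrays limma called 0 genes (544 at an unadjusted p under 0.05, smallest adjusted p = 0.229, that of Slco2b1), and 0 with scan day as a block (1248, 0.183). In the test on simulated data the interaction with 10 arrays recovered 1% of genes changed 4-fold, so a count of 0 here does not show equal responses.

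Camera called 10 lists for the interaction as labelled. The cAMP list (median -1.64, adjusted p = 1.29e-11, 0 of 34 positive) and the interferon list (median 0.77, adjusted p = 1.43e-06, 30 of 34 positive) were also called without the 2 arrays, at medians of -0.66 and 0.88. Both had adjusted p = 0.692 with an estimated correlation, and 0.976 without the 2 arrays. Their within-day medians were -0.42 and -1.02 for the cAMP list and 0.42 and 1.29 for the interferon list. With 12 arrays 2 cAMP-responsive genes were called when adjusted over the list alone, and with 10 arrays 0; over all genes limma called 0 members of either list. Mast cell markers had a median of 0.19 in both fits and were not called. The other 8 lists, led by NF-kappaB targets and glycolysis genes, had medians of -1.17 to -0.60 and adjusted p of 1.47e-07 to 0.0167 as labelled, but adjusted p = 0.692 with an estimated correlation. Without the 2 arrays none of the 8 was called, and glycolysis had the opposite sign (0.25 against -1.17).

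Across genes, the genotype difference in unstimulated cells and that in stimulated cells had a Pearson's r of -0.091 as labelled (rho -0.15), of 0.287 without the 2 arrays (rho 0.248) and of 0.309 with scan day as a block (rho 0.305). Genes that kept their sign in both states include Cxcl13, at 2.74 and 2.70 in unstimulated and 2.56 and 2.60 in stimulated cells within the scan days, Marco, at 2.75 and 2.52 and then 2.71 and 2.88, and Cpa3, at -3.10 and -3.56 and then -2.57 and -3.34. These 3 were singled out after their values were seen.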

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

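The tests in this part were chosen after the results were seen, apart from the counts of genes under other splits of the arrays, which were planned.

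Slco2b1, an organic anion transporter, stood out because its response to the yeast was called as different between the genotypes (fitted value -4.23, log2, limma interaction on 12 arrays as labelled, adjusted p = 0.0244). It was well above background on the 3 stimulated cPLA2a+/+ arrays and on 0 of the other 9, so the fitted value rests on signals near background and is no measure of size, and with normexp it was 0.18. For the same reason 10 gene lists stood out, with these median differences between the responses (cPLA2a-/- minus cPLA2a+/+, camera on 12 arrays): cAMP-responsive genes -1.64, glycolysis and hypoxia -1.17, anti-inflammatory feedback -1.11, cytokines -1.10, NF-kappaB targets -0.95, chemokines -0.90, heat shock -0.89, matrix and coagulation -0.74, endoplasmic reticulum stress -0.60 and interferon-stimulated genes 0.77. Their camera adjusted p ran from 1.29e-11 to 0.0167, and each had adjusted p = 0.692 with an estimated correlation. Without the 2 arrays that stood apart, 2 of the 10 lists were called, the cAMP list at -0.66 and the interferon list at 0.88.

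The first pattern is the position of the arrays labelled cPLA2a-/- unstimulated replicate 3 and cPLA2a-/- stimulated replicate 3, which stood apart from their groups. The tables argue against mixed RNA of the 2 wells, since both arrays lay near an end of the axis from unstimulated (0) to stimulated (1) cells, the nearer one at a distance of 0.538 from its middle. They also argue against an exchange with a cPLA2a+/+ array: the higher of the 2 arrays had a mean mast cell marker level of -1.17 (log2) relative to the lowest of the 6 cPLA2a+/+ arrays. An exchange of the 2 labels with each other stays open as a candidate explanation, with the first array at 1.11 and the second at -0.038 on the axis, each among arrays of the other state. As labelled, slide 1 held stimulated cPLA2a-/- replicates 2 and 3, and slide 2 held unstimulated cPLA2a-/- replicates 2 and 3. With the labels exchanged, each of these slides would hold all 4 groups, a layout that does not rest on the expression values. The exchange was found and tested on the same data, and no biological explanation was tested. No value with exchanged labels is given apart from 1 split of the arrays at the end of this part.

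The second pattern is the lower level of mast cell markers in cPLA2a-/- cultures, of which Cma1 stood at 3.24 ± 0.60 in unstimulated cPLA2a+/+ cells and at 0.03 ± 0.70 in unstimulated cPLA2a-/- cells, and Cpa3 at 1.66 ± 0.44 and -1.79 ± 0.85 (log2, SD, n = 3 and, without the array that stood apart, n = 2). The tables argue against scan day, since the within-day median nearest to 0 was -2.01. They also argue against the choice of scaling, since the median nearest to 0 under quantile, median and normexp values was -1.17 (normexp). The deposited values were tried too, but they follow the scaling used here and are no separate check. A loss of all other peritoneal cells alike is argued against by the lowest median among the 5 other cell type lists in unstimulated cells, -0.38 (B cells, 10 arrays; -0.57 within the second scan day). Hdc, 1 of the 12 markers, can also be made by stimulated macrophages, none of the 12 stands in another list, and no sort or gate that would remove mast cells is named in the sources used here. A smaller number of mast cells among the adherent cells of cPLA2a-/- mice, or a lower expression of these genes in each mast cell, stays open as a hypothesis, and cell numbers were not analysed here.

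The third pattern is the lower cAMP-responsive list and the higher interferon-stimulated list in stimulated cPLA2a-/- cells (medians -0.85 and 1.07 with 10 arrays, camera adjusted p = 1.04e-09 and 7.15e-14, and adjusted p = 0.548 for each with an estimated correlation). The tables argue against scan day, as the within-day medians nearest to 0 were -0.70 and 1.11 for these lists. A response weaker by 1 factor for every gene was also examined (slope 0.877 over 3398 genes). These were genes called in either response and outside both lists, while the slope over all 18914 genes was 0.978. The median interaction beyond that factor was -0.49 for the cAMP list (interquartile range -0.87 to -0.14) and 0.79 for the interferon list (0.38 to 1.05). Most members thus lay on 1 side of the factor. These ranges are a spread between genes, which are not independent, and give no spread between arrays. For the interaction on 10 arrays limma called 0 genes, and camera with an estimated correlation called 0 of 28 lists. The test therefore does not decide on this explanation. For the interferon list the test of fewer mast cells does not decide. Missing mast cell RNA would raise this list and the resident macrophage list alike, and the latter had a median of -0.13 (-0.32 to 0.24). The values show only that the lists did not rise alike, since the scaling of each array can take out a shared rise. An effect of mast cells on interferon-stimulated genes of the macrophages was not tested. Fewer mast cells therefore stay open for the interferon list. For the cAMP list an effect of fewer mast cells and a change in the macrophages cannot be told apart. The list's median in unstimulated cells was -0.24, and -0.405 and 0.12 within the scan days. Genes that mast cells switch on only when stimulated escape this test. A lower supply of prostaglandins, which raise cAMP in macrophages, is a hypothesis that stays open for both lists, with lipid mediators not analysed here and the lists seen and tested on the same data.

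Other splits of the arrays were counted for each number of genes called by limma. For the interaction, 6 of 100 splits of the genotypes within each state, the real one and 99 drawn ones, called at least the 1 gene of the real one, so chance cannot be excluded; the highest other split called 1846, which points to a structure of the samples. The 6 arrays of a comparison of 2 groups have 10 splits, too few for a share under 0.05. The real split called 9 genes and the highest other 0 in the cPLA2a+/+ response with 12 arrays (1 of 10 splits gave as many), 3252 and 0 on the 6 cPLA2a+/+ arrays (1 of 10), 9 and 0 between the stimulated genotypes (1 of 10) and 0 and 0 between the unstimulated genotypes (10 of 10). In the cPLA2a-/- response the real split called 0 genes (334 at an unadjusted p under 0.05; 10 of 10 splits gave as many). The highest other split there called 3716, with unstimulated replicates 1 and 2 and stimulated replicate 3 on 1 side, which is the comparison with the 2 labels exchanged and points to a structure of the samples, that of the first pattern.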

How the results depend on the processing

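The settings with 10 arrays, that is without the arrays labelled cPLA2a-/- unstimulated replicate 3 and cPLA2a-/- stimulated replicate 3, were chosen after the data were seen. Every other setting was fixed before, apart from the use of the median signal in normexp. Where a result changed and nothing else is said, the cause was not tested. The labels do not say what a replicate number marks, and the numbers were not taken to pair the samples. After group means were removed, 11 of 18 pairs of arrays with the same number had a correlation over 0.1 (median 0.163, highest 0.632). The lowest, -0.639, was that of the 2 arrays that stood apart. These arrays also shift the means of their groups, so the count with 12 arrays cannot decide on pairing. With 10 arrays 12 of 13 such pairs did (lowest -0.232, median 0.304, highest 0.6), and 4 of 24 pairs with different numbers. Those 4 were among the 6 such pairs that share a scan day (median 0.364), and not every array correlated best with one of its own number. All 4 also share a slide, while the remaining same-day pairs, at 0.093 and -0.032, do not. Fitted as a random term on 10 arrays, slide had a consensus correlation of 0.603. Slide does not cover every pair, since the cPLA2a+/+ arrays of replicate 2 stood on different slides and correlated at 0.271. With 10 arrays each cPLA2a-/- group has 2 arrays, whose values mirror each other once the group mean is removed. The counts for the same and for different numbers are therefore tied to each other. The second scan day holds replicate 1 of every group, so number and scan day are tied as well. Apart from the mast cell list above, the replicate block is given here alone. With it the mast cell and metal handling lists in unstimulated cells each had adjusted p = 0.094 with an estimated correlation. Over the values of single genes and gene lists under all settings, 3971 kept their direction and their side of the threshold, 574 kept their direction and were called in addition, 284 kept their direction and lost the call, and 59 changed sign. Array weights gave the lowest weight, 0.335, to the array labelled stimulated cPLA2a-/- replicate 3. The share of spots well above background, 56.1% to 76.6%, limits which genes can be tested on an array.

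The number of genes called by limma in the cPLA2a+/+ response, 9 with 12 arrays as labelled, was 75 with normexp, 14 with quantile scaling and with replicate number as a random term, 1 with median scaling and with a replicate block, 4 without a filter, 19 with every probe on its own, 17 with a scan day block, 0 with a slide block and 5770 with array weights. It was 3252 on the 6 arrays compared, 3320 with 10 arrays, 5475 with 10 arrays and a scan day block and 5755 with 10 arrays and slide as a random term. Leaving out 1 array or replicate number gave 0 to 841, the most without unstimulated cPLA2a-/- replicate 3. In the cPLA2a-/- response, 0 as labelled, it was 1195 with 10 arrays, 3208 with a scan day block added and 2206 with slide as a random term, and 0 to 210 with 1 array or number left out, the most without replicate 3.

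Between unstimulated genotypes, 0 as labelled, limma called 1 gene with normexp, 2 with a replicate block and 2 with 10 arrays and slide as a random term. Between stimulated genotypes, 9 as labelled, it called 19 with quantile scaling, 0 with median scaling, 1 without a filter, 23 with every probe on its own, 5 with a replicate block, 14 with trend and robust moderation, 78 with array weights, 0 with a slide block, 18 with a scan day block and 0 on the 6 arrays compared. With 10 arrays it called 4, with a scan day block added 190 and with slide as a random term 283; leaving out 1 array or number gave 0 to 16, the most without unstimulated cPLA2a-/- replicate 2. For the interaction, 1 as labelled, it called 0 with normexp, quantile or median scaling, no filter, the filter over all 12 arrays, a replicate, slide or scan day block, trend and robust moderation, and each of the 3 fits with 10 arrays; leaving out 1 array or number gave 0, or 1 without stimulated cPLA2a-/- replicate 1.

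The genotype difference of Pla2g4a in unstimulated cells, -1.35 as labelled, was called with 10 arrays and slide as a random term (-2.45). In stimulated cells, -2.70 as labelled, it was called with 10 arrays and a scan day block (-1.55) and with slide as a random term (-1.75). The correlation of the 2 responses across genes, 0.45 as labelled, was 0.733 with 10 arrays, with and without a scan day block, and ran from -0.265 without replicate 2 to 0.671 without stimulated cPLA2a-/- replicate 3. That of the genotype differences, -0.091 as labelled, was 0.287 with 10 arrays and 0.309 with a scan day block added, and ran from -0.388 without replicate 1 to 0.231 without stimulated cPLA2a-/- replicate 3.

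The number of lists called by camera was 12 in the cPLA2a+/+ and 10 in the cPLA2a-/- response and 0 in both with an estimated correlation, with fry, and with an estimated correlation on 10 arrays, with and without a scan day block or with median scaling. With quantile scaling of the 10 arrays and an estimated correlation it was 6 and 5, and with fry on the 10 arrays 11 and 10. Between unstimulated genotypes, 16 as labelled, it was 2 with an estimated correlation, 1 with fry, 6 with 10 arrays, also with quantile scaling, 5 with median scaling and 7 with a scan day block added, 1 with 10 arrays and fry, and 0 with 10 arrays and an estimated correlation, with and without a scan day block or either scaling. Between stimulated genotypes, 7 as labelled, it was 0 with an estimated correlation, 1 with fry, 4 with a replicate block, 4 with 10 arrays, also with quantile scaling, 1 with 10 arrays and fry, and 0 with 10 arrays and an estimated correlation, with and without a scan day block or either scaling. For the interaction, 10 as labelled, it was 0 with an estimated correlation and with fry, 2 with 10 arrays, also with either scaling, 3 with a scan day block added, and 0 with 10 arrays and fry or an estimated correlation, the latter also with a scan day block or either scaling.

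Many of the single values that changed sign belong to the cPLA2a-/- response, and a part of these to the fit without replicate 2, which leaves each cPLA2a-/- group 2 arrays, 1 of them an array that stood apart. Over the fits with 1 array or number left out, with the lowest value without replicate 2 and the highest without replicate 3, the responses ran from -0.19 to 7.34 for Csf3, -0.48 to 6.99 for Ptgs2, -1.34 to 6.90 for Csf2, -0.43 to 6.73 for Ccl7, -0.26 to 6.64 for F3, -0.99 to 6.40 for Gdf15, -0.36 to 6.19 for Tnf, -0.49 to 5.23 for Ccl2, -0.028 to 4.88 for Cxcl1, -0.05 to 3.40 for Pla2g4a, -0.59 to 2.56 for Il10, -0.037 to 4.77 for Il6, -0.39 to 4.87 for Hk2, -0.35 to 5.62 for Il1a, -0.32 to 6.13 for Gem, -0.044 to 5.46 for Il1rn, -0.026 to 4.43 for Ccl3 and -1.54 to 6.30 for Edn1. With the lowest value without replicate 3 and the highest without replicate 2, they ran from -4.20 to 0.82 for Engase, -3.50 to 0.71 for Bmf, -3.21 to 0.094 for Thbd, -3.31 to 0.21 for Bahcc1 and -3.01 to 0.43 for Axin2. Irf4 ran from -0.086 without replicate 1 to 3.93 without replicate 3, and Ptgs1 from -0.31 without stimulated replicate 3 to 0.95 without stimulated replicate 1. With a slide block Csf2 was at -0.061, Bmf at 0.58 and Il10 at -0.56; with normexp Axin2 was at 0.002; and with 10 arrays Ptgs1 was at -0.20, with and without a scan day block, and at -0.13 with slide as a random term.

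Between stimulated genotypes Tnf, -0.24 as labelled, was at 0.91 with array weights, 1.94 with 10 arrays, 2.04 with a scan day block added and 2.03 with slide as a random term, and ran from -1.62 without stimulated cPLA2a-/- replicate 2 to 2.29 without replicate 3. Adm was at -0.77 with a slide block and ran from -1.03 without stimulated cPLA2a-/- replicate 1 to 1.91 without stimulated cPLA2a-/- replicate 3. With normexp Slco2b1 was at -0.79 between unstimulated genotypes and at 0.18 for the interaction.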

Other observations

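The test of genes near the targeted locus was set before its result was seen, on a fit that, like the others in this part, was chosen after the data were seen.

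Beside the lists already described, 6 more lists were called by camera in the response of cPLA2a-/- cells to the yeast (10 arrays). All 14 measured heat shock genes had a positive difference (median 0.68), and limma called 0 of them (0 adjusted over the list alone). Of 22 oxidant defence genes 5 rose (median 0.35, 6 adjusted over the list alone), of 20 metal handling genes 5 (0.36, 5 adjusted over the list alone), of 18 antigen presentation genes 3 (0.32, 3), of 18 alternative activation genes Irf4, a transcription factor, by 3.93 (0.49, 1), and of 35 fungal recognition genes 1 (0.17; 5 rose and 1 fell adjusted over the list alone). Their camera adjusted p ran from 0.000108 for heat shock to 0.0282 for fungal recognition, and from 0.12 to 0.694 with an estimated correlation. Edn1, the precursor of the vasoconstrictor endothelin 1, rose by 6.30 ± 0.91 (SE, 2 against 2 arrays, adjusted p = 0.00832).

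Among the genes that differed between stimulated genotypes with scan day as a block (10 arrays, 2 against 3) were several outside the lists. Lepr, the leptin receptor, fell by 4.40 ± 0.59 and Npy, neuropeptide Y, by 2.94 ± 0.32, while the neurotrophic factor gene Artn rose by 3.21 ± 0.46, Tnfsf4, the OX40 ligand, by 2.97 ± 0.44 and the glutathione transferase gene Gsta3 by 2.76 ± 0.40 (SE, adjusted p from 0.0336 to 0.0397). Of 25 chemokines 2 rose in this fit (median 0.44, 3 adjusted over the list alone), of 18 antigen presentation genes the costimulatory receptor gene Cd40, by 1.24 (0.35), of 24 glycolysis and hypoxia genes 2, with Adm, adrenomedullin, by 1.79 (0.21), and of 20 metal handling genes 2, with Tfrc by 1.51 (0.23). The direction of Adm was not steady, at 0.07 with 12 arrays as labelled and at -1.03 without stimulated cPLA2a-/- replicate 1. Cd40 and Tnfsf4 kept their direction in the fits with 1 array or number left out, but ran from 0.40 to 1.19 and from 0.89 to 3.25. Within the scan days the list medians were 0.38 and -0.04 for glycolysis and hypoxia and 0.27 and 0.49 for chemokines. They were 0.34 and 0.54 for antigen presentation and 0.295 and 0.13 for metal handling. Camera gave these 4 lists an adjusted p of 0.0195 to 0.038, and with an estimated correlation the adjusted p lay between 0.545 and 0.768. Mast cell markers were lower in the same fit, by a median of -2.19.

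Of the 189 genes called in that fit, Pla2g4a left out, 3.17% lay on chromosome 1 within 20 Mb of Pla2g4a, against 1.39% of all tested genes with a position. This argues against a local effect of DNA from another strain, on the genes within that window, as the source of the whole set. Effects of such DNA on genes elsewhere in the genome were not tested. For the 6 genes in this window, Kcnt2, Rgs1, Rgs2, Tnfsf4, Prdx6 and Tdrd5, a local effect stays open. Of these, 2, Rgs1 and Rgs2, belong to the cAMP-responsive list.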
